A study of Mus musculus with 12 samples.

How the data were processed

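Gene expression in mouse cells was measured on 12 single-colour Agilent arrays, each hybridized with RNA carrying an Alexa Fluor dye. Per the labels, the arrays fall into 5 groups: primary myofibroblasts of hepatic stellate cell origin (Pr-mHSC, 2 arrays), hepatocytes induced from myofibroblasts in the animal (In-vivo iHep, 3), endogenous hepatocytes of the animal (In-vivo eHep, 3), hepatocytes induced from myofibroblasts in culture (In-vitro iHep, 3) and primary hepatocytes after a day in culture (PH24h, 1). All 12 arrays were used, and the groups and replicate numbers were taken from the labels.

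Per the file headers, the deposited scanner files hold the intensity of each spot as made by Feature Extraction 10.7.3.1. That software subtracted a spatial trend of the background within the array, corrected a multiplicative trend and put a surrogate in place of spots near background. Per the file headers, the authors applied no scaling between arrays to this intensity. The deposited matrix of the authors holds log2 values. Its 12 columns share a maximum of 16.93 and have nearly equal quartiles, as quantile normalization gives, and they correlate with the log2 intensity of the same array at r = 0.994 to 0.9995 across probes. The submitters' processing notes name lumi. Its version, and the method behind the matrix, are not given in the sources used here.

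The values used here were computed from the processed intensity. Spots marked as non-uniform or as outliers were left out, and no spot was saturated. The intensities were put on the log2 scale and averaged over spots of the same probe, and the 75th percentile of each array was set to 0, so that every level below is a log2 distance from the upper quartile of its array. Of 39429 probes that are not controls, 31276 were well above background, per the scanner software, on at least 2 arrays and were kept. Each of the resulting 25075 genes was represented by its probe with the highest mean. There were 5166 genes with more than 1 kept probe. Names came from the accession of the array design (26412 probes), a current symbol (3854), a single synonym (735) or, without a match, the name in the design (8428), through RefSeq names of GRCm38.p6 used for naming alone. A RefSeq symbol was matched by 19695 of the genes tested and by 5380 it was not. Probe coordinates are those of the array design, in mm9, per the file headers.

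Differences were estimated in R 4.3.3 with limma 3.58.1, with the data.table package (version 1.17.8) for reading files. A single linear model with a mean for each of the 5 groups was fitted to all 12 arrays, so that every comparison shares an estimate of the spread, followed by empirical Bayes moderation. P values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called higher or lower at an adjusted p under 0.05 with an absolute log2 difference of at least 1. There were 6 comparisons of groups, and a contrast that set the gap between In-vivo iHep and In-vivo eHep against the gap between In-vitro iHep and PH24h. PH24h has no replicate, and its array was assumed to vary like the arrays of the other groups. Where no array of a group was above background, the fold is given as a lower bound, set against the signal at the background limit, and written as at least.

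Lists of genes for hepatocyte functions, stellate cells and matrix, other cells of the liver and general processes were written and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The test was repeated with a correlation estimated from the data and with fry. Counts of called members are given over all genes tested and, where different in the direction of the list, adjusted over the list alone. The position of each array between Pr-mHSC and In-vivo eHep was the median, over genes called between these groups, of the array's distance from the Pr-mHSC mean divided by the distance of the In-vivo eHep mean. Arrays of those end groups were placed with genes and means recomputed without them. The overlap of calls between comparisons with the same controls was set beside that of independent lists, and the correlation and covariance of their differences beside 100 simulations of unchanged groups.

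The comparisons, tests, thresholds, lists and alternatives were chosen before the data were examined, except for 6 further lists: mesothelial, brush border, digestive transcription factors, abundant kidney transcripts, abundant intestinal transcripts, and Y-linked genes with Xist, and for the tests of technical explanations, the tests of those lists without the members already seen, and the overlap with separate controls. The named genes also follow a rule set then: the 5 largest rises and falls among called genes with an official-looking symbol and no overlap of arrays, the largest called rises and falls and the nearest miss of each list discussed, and Foxa3, Gata4, Hnf4a, Alb, Ttr, Cyp3a11, Afp, Krt19, Acta2, Col1a1, Vim and Mki67 in every comparison. Some genes that this rule takes are not reported here. Every gene named below as higher or lower had no overlap of arrays between the groups compared. Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' matrix, no filter on dim probes, a stricter filter, the mean of a gene's probes, only the groups compared, array weights, a robust trend, the slide or the replicate number as a block, a log2 difference of at least 2, and leaving out each array in turn.

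The code was tested on simulated data with the means and spread of 24959 genes. Of 100 genes with a planted log2 difference of 3, the share recovered was 75% for In-vivo iHep versus Pr-mHSC, 79% for In-vitro iHep versus Pr-mHSC, 81% for In-vivo eHep versus Pr-mHSC, 83% for In-vivo iHep versus In-vivo eHep, 50% for In-vitro iHep versus PH24h and 86% for In-vivo iHep versus In-vitro iHep. For a planted difference of 1.5 the shares were, in the same order, 14%, 13%, 12%, 21%, 2% and 25%. Only 100 genes of each size were changed, far fewer than were called in the data. The adjustment of p values was therefore stricter than in the data, and these shares do not give the share recovered there. Depth is the signal above background, and the number of arrays limits the precision.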

Results

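Gene expression was profiled in myofibroblasts, in hepatocytes, and in hepatocyte-like cells induced from myofibroblasts either in the mouse or in culture. The data comprised 12 arrays: 2 of primary myofibroblasts of hepatic stellate cell origin (Pr-mHSC), 3 of hepatocytes induced from myofibroblasts in the animal (In-vivo iHep), 3 of the animal's own hepatocytes (In-vivo eHep), 3 of hepatocytes induced in culture (In-vitro iHep) and 1 of primary hepatocytes after a day in culture (PH24h). The share of probes well above background was 69.4% and 69.0% in Pr-mHSC, 67.6%, 67.6% and 65.2% in In-vivo iHep, 62.8%, 61.1% and 69.6% in In-vivo eHep, 71.9%, 67.2% and 76.9% in In-vitro iHep and 57.2% in PH24h. The upper quartile of the scanner signal ran from 1861 in PH24h to 7419 in In-vitro iHep replicate 3. Levels below are log2 signals relative to that quartile of the same array, with the SD between arrays.

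The labels do not say whether replicates came from separate animals, so the p values measure the spread between these samples only. Pr-mHSC, In-vivo iHep and In-vivo eHep shared 3 slides scanned on the same day. The In-vitro iHep arrays were scanned on another day and PH24h on a further day with another scanner, so for every comparison across those days, scan day and group cannot be told apart. The in-vivo groups came from mT/mG reporter mice and the other groups from Balb/c AnNCrl mice, so strain goes with the in-vivo setting. The labels do not give the sex of the animals. Ddx3y and Eif2s3y, which are Y-linked, were above background on every array but PH24h. Xist was above background on In-vivo iHep replicate 1, In-vivo eHep replicate 1, every In-vitro iHep array and PH24h. Sex may thus differ between the groups compared. The median difference over all genes tested was 0.11 for In-vivo iHep versus Pr-mHSC, 0.15 for In-vitro iHep versus Pr-mHSC, 0.40 for In-vivo eHep versus Pr-mHSC, -0.39 for In-vivo iHep versus In-vivo eHep, 0.00 for In-vitro iHep versus PH24h and 0.00 for In-vivo iHep versus In-vitro iHep.

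Foxa3, Gata4 and Hnf4a encode hepatocyte transcription factors that are used to induce hepatocyte-like cells. The Hnf4a probe (chromosome 2, 163398548 to 163398607, mm9) was not above background on either Pr-mHSC array, and its level was 4.73 ± 0.58 in In-vivo iHep (n = 3), 5.66 ± 0.19 in In-vivo eHep (n = 3), 3.40 ± 0.85 in In-vitro iHep (n = 3) and 5.55 in PH24h. Foxa3 (chromosome 7, 19599053 to 19599112) had a level of 2.33 ± 0.69 in In-vivo iHep, 2.69 ± 0.33 in In-vivo eHep, -4.68 ± 1.40 in In-vitro iHep, -0.13 in PH24h and -6.74 ± 0.98 in Pr-mHSC (n = 2). Gata4 (chromosome 14, 63817858 to 63817917) had its highest mean, 1.28 ± 0.67, in Pr-mHSC and means of -1.05 ± 0.31 in In-vivo iHep, -1.02 ± 0.16 in In-vivo eHep, -0.98 ± 0.13 in In-vitro iHep and -1.95 in PH24h. Whether these probes detect copies of the genes delivered to the cells is not known.

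The position of each array between myofibroblasts and hepatocytes was measured over the 12057 genes called between Pr-mHSC and In-vivo eHep, with 0 at Pr-mHSC and 1 at In-vivo eHep. Some of these genes were above background in neither end group, so their levels there depend on the upper quartile of each array. Cdx2, an intestinal regulator, was among them and was not above background in In-vivo iHep either. It still read -8.86, -8.44 and -8.53 there, between -9.58 and -9.39 in Pr-mHSC and -7.94, -7.71 and -8.28 in In-vivo eHep. The positions were not computed without such genes. In-vivo iHep lay at 0.567 ± 0.110 (n = 3), In-vitro iHep at 0.251 ± 0.087 (n = 3) and the PH24h array at 0.498. Arrays of the end groups, placed without themselves, lay at 0.0616 ± 0.0544 for Pr-mHSC (n = 2) and 0.960 ± 0.142 for In-vivo eHep (n = 3). Every In-vivo iHep array lay above every In-vitro iHep array, with a difference of means of 0.317, and the two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. Genes higher in hepatocytes placed In-vivo iHep at 0.537 and In-vitro iHep at 0.239, and genes higher in myofibroblasts placed them at 0.636 and 0.290. PH24h lay at 0.397 on the former genes and at 0.728 on the latter. Across genes, which are not independent replicates, In-vivo iHep arrays correlated with In-vivo eHep at a mean r of 0.918 and with Pr-mHSC at 0.811. In-vitro iHep correlated with Pr-mHSC at 0.877, with PH24h at 0.838 and with In-vivo iHep at 0.840, against 0.965 to 0.983 within groups.

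**Figure D1:**
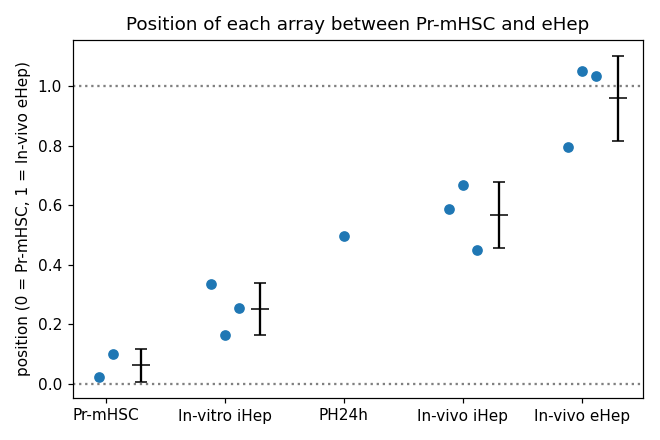
Position of each array between myofibroblasts (0) and endogenous hepatocytes (1), as the median over 12057 genes of the fraction of the distance covered; dots are arrays, bars the group mean and SD, and PH24h is a single array. In-vivo iHep lies at 0.567 and In-vitro iHep at 0.251, with no overlap of their arrays. Some of the genes were above background in neither end group.

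The comparison of In-vivo iHep with Pr-mHSC asks how cells converted in the animal differ from primary myofibroblasts, which came from mice of another strain. Products of hepatocytes rose by the widest margins. Alb, the main plasma protein, had a level of 7.05 ± 0.33 in In-vivo iHep (n = 3) and -7.36 ± 0.70 in Pr-mHSC (n = 2), a log2 difference of 14.41 (SE 0.65, adjusted p = 1.97e-07). Fga, a fibrinogen chain, was at least 12969-fold higher in In-vivo iHep, the protease inhibitor Serpina3k at least 14527-fold, the fatty acid carrier Fabp1 at least 12977-fold, the lipoprotein gene Apoa1 at least 15591-fold and the urinary protein gene Mup5 at least 14140-fold. In the list of plasma proteins, 35 of 36 genes rose, with a median difference of 11.96 (adjusted p = 5.64e-33), and F10 did not pass the test at 0.59 although its other probe read 13.6. All 24 cytochrome P450 genes rose, with a median of 11.01 (adjusted p = 2.23e-21), among them Cyp2f2 (at least 8841-fold), Cyp3a25 (at least 6396-fold) and Cyp3a11 (at least 14087-fold). All 28 genes of the urea cycle and amino acid metabolism rose, with a median of 10.35 (adjusted p = 3.52e-27), including Arg1, which splits arginine in the last step of the cycle (at least 3605-fold). Of the hepatocyte transcription factors, 18 of 23 rose, Gata4 fell by 2.32 and 4 did not pass, with a median of 6.22 (adjusted p = 1.31e-11). Hnf4a was at least 3965-fold higher, Foxa3 rose by 9.07, and the plasma protein Ttr was at least 12272-fold higher. Among junction genes, 18 of 19 rose, led by the keratins Krt8 (at least 12213-fold) and Krt18 (13.14), with a median of 7.04 (adjusted p = 1.94e-16). For each of these 5 lists the adjusted p was 0.0907 with an estimated correlation. Afp, a fetal plasma protein, rose by 3.54 (adjusted p = 0.00258) and the biliary keratin Krt19 by 6.39 (adjusted p = 0.0001).

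Genes of myofibroblasts fell in the same comparison. In the list of extracellular matrix genes, 21 of 32 fell, 25 when adjusted over the list alone, and the rest did not pass, with a median of -3.75 (adjusted p = 4.96e-11, and adjusted p = 0.151 with an estimated correlation). Thbs2 fell by 7.92 and Tnc, a matrix protein of wounds, by 6.78. Col1a1, the main fibrillar collagen, had a level of 1.64 ± 1.07 in In-vivo iHep and 5.35 ± 0.14 in Pr-mHSC and did not pass the test (adjusted p = 0.0738), although it passed with median centring and with normexp. In the list of activated stellate cells and myofibroblasts, 18 of 27 genes fell and 9 did not pass, with a median of -4.16 (adjusted p = 6.58e-09, and adjusted p = 0.22 with an estimated correlation). The contractile genes Cnn1 and Actg2 fell by 7.62 and 7.03. Acta2, smooth muscle actin, fell by 4.18 (adjusted p = 0.0452), a call lost without Pr-mHSC replicate 2 (0.142) or 3 (0.155), without In-vivo iHep replicate 1 (0.116) or 3 (0.092), and with slide as a block (0.0776). The matrix-degrading protease Mmp10 fell at least 781-fold, to below background, and among the other largest falls Ccdc3 fell by 8.53, Syt13 at least 73.8-fold and Tbx20, a cardiac transcription factor, at least 106-fold. Of 20 genes of quiescent stellate cells, 13 fell, 14 when adjusted over the list alone, with a median of -2.66 (adjusted p = 0.000338, and adjusted p = 0.339 with an estimated correlation). Des fell by 5.41 and Lhx2 by 6.04, while Plin2, a lipid droplet protein, rose by 2.54 and Pparg, a regulator of fat storage, by 4.64. Vim, a mesenchymal filament gene, had levels of 3.52 ± 0.29 and 5.08 ± 0.26 and did not pass (adjusted p = 0.341), nor did the proliferation marker Mki67 (adjusted p = 0.719).

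Markers of other liver cells were also higher in In-vivo iHep than in Pr-mHSC. In the list of macrophages and Kupffer cells, the resident macrophages of the liver, 21 of 22 genes rose, with 1 lower when adjusted over the list alone and a median of 7.11 (adjusted p = 7.33e-13, and adjusted p = 0.184 with an estimated correlation). Clec4f, a Kupffer cell lectin, was at least 2153-fold higher and Cd5l at least 2332-fold. Itgam did not pass (adjusted p = 0.0614). Of 22 endothelial genes, 18 rose and 1 fell, with a median of 4.52 (adjusted p = 4.64e-08, and adjusted p = 0.22 with an estimated correlation), and the sinusoidal markers Clec4g and Stab2 rose by 9.11 and 8.65. In all, 3942 genes were higher and 3217 lower in In-vivo iHep, and for 1257 of the former Pr-mHSC was not above background on any array. The higher share, 55.1%, became 39.4% with median centring (3177 higher and 4876 lower), and without Pr-mHSC replicate 2 the counts were 2626 and 1902. With slide as a block, 2841 genes were higher and 1867 lower. Within slides 2 and 3, which hold both groups, the plasma protein list had medians of 12.57 and 11.48, the macrophage list 7.70 and 6.87 and the matrix list -3.75 and -3.67.

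Conversion in culture was examined in the comparison of In-vitro iHep with Pr-mHSC. Liver products rose here too. Apoa1 rose at least 7600-fold, Ttr, a thyroid hormone carrier, at least 2340-fold and Alb by 12.48, from -7.36 ± 0.70 (n = 2) to 5.12 ± 1.35 (n = 3; SE 0.65, adjusted p = 1.25e-06). Afm, a carrier of vitamin E, rose at least 3303-fold. Hnf4a rose at least 1571-fold and Foxa2, a pioneer factor of endoderm, at least 296-fold, whereas Foxa3 did not pass the test (2.06, adjusted p = 0.0895) and Gata4 fell by 2.26 (adjusted p = 0.000796), a call lost with the replicate block (0.0738). Of 36 plasma proteins, 24 rose, 25 when adjusted over the list alone, 2 fell and 10 did not pass, with a median of 4.62 (adjusted p = 1.03e-13, and adjusted p = 0.469 with an estimated correlation). Cytochrome P450 genes rose in 11 of 24 cases, 12 when adjusted over the list alone, with a median of 1.79 (adjusted p = 1.68e-06, and adjusted p = 0.469 with an estimated correlation). Cyp2f2 rose at least 165-fold, Cyp2a12 at least 98.0-fold and Cyp3a11, a main drug-metabolizing enzyme, at least 42.7-fold (lost with the replicate block, 0.067), while Cyp3a25 did not pass (adjusted p = 0.0903). In the list of the urea cycle and amino acids, 13 of 28 genes rose, 14 when adjusted over the list alone, and 2 fell, with a median of 1.60 (adjusted p = 0.00137, and adjusted p = 0.6 with an estimated correlation).

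Epithelial and fetal liver genes rose in In-vitro iHep as well. Of 19 junction genes, 12 rose, 13 when adjusted over the list alone, with a median of 3.90 (adjusted p = 4.11e-10, and adjusted p = 0.469 with an estimated correlation). Cldn2, a pore-forming claudin, was at least 1342-fold higher and Ocln at least 109-fold. Krt19 rose by 8.04 (adjusted p = 2.99e-05). Of 15 fetal liver genes, 7 rose, Mest fell by 5.39 and 7 did not pass, with a median of 1.40 (adjusted p = 0.00339, and adjusted p = 0.469 with an estimated correlation). Afp rose by 8.18 and Gpc3, an oncofetal proteoglycan, at least 18.6-fold, while H19 did not pass (adjusted p = 0.152). The remaining members of the 5 largest rises were Vil1, a microvillus protein (at least 2508-fold), Tspan8 (at least 1926-fold) and Clic6 (at least 2199-fold).

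Stellate cell and matrix genes fell in culture. Of 20 genes of quiescent stellate cells, 15 fell, Pparg rose by 4.59 and 4 did not pass, with a median of -3.90 (adjusted p = 1.12e-09, and adjusted p = 0.469 with an estimated correlation). Lrat, which stores vitamin A as an ester, fell at least 544-fold and Tcf21, a mesenchymal transcription factor, at least 2692-fold. The receptor gene P2ry14 fell at least 4679-fold, Bco1, which cleaves beta-carotene, at least 2800-fold, Gdf2 at least 2402-fold and Robo2 at least 1044-fold. Of 32 matrix genes, 16 fell, 18 when adjusted over the list alone, Fbln1 rose by 4.28 and 15 did not pass, with a median of -2.74 (adjusted p = 5.75e-09, and adjusted p = 0.469 with an estimated correlation). Lum fell by 12.36 and Col14a1 by 7.97, while Col1a1 did not pass (-2.59, adjusted p = 0.263). Of 27 genes of activated stellate cells and myofibroblasts, 12 fell, 14 when adjusted over the list alone, with a median of -2.61 (adjusted p = 2.72e-07, and adjusted p = 0.469 with an estimated correlation), led by the contractile genes Myl9 (-10.61) and Cnn1 (-10.05). Acta2 fell by 4.97 (adjusted p = 0.0319), a call lost without Pr-mHSC replicate 2 (0.108) or 3 (0.147) without In-vitro iHep replicate 1 (0.0871) or 3 (0.103), and with the replicate block (0.114). Vim had levels of 4.99 ± 0.23 and 5.08 ± 0.26 (adjusted p = 0.974), and Mki67 did not pass (adjusted p = 0.883). The macrophage list had a median of 0.14, with a mean of -0.02 and a test direction of down (adjusted p = 0.482), a sign that changes with the scaling. In total, 2474 genes were higher and 2034 lower in In-vitro iHep, and for 771 of the former Pr-mHSC was not above background. With the replicate block the counts were 967 and 781. The higher share, 54.9%, became 48.0% with median centring (2195 and 2375), 48.4% with normexp (1909 and 2031) and 49.7% in the authors' matrix (2275 and 2305).

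The calls of the pair of iHep comparisons with Pr-mHSC overlapped. There were 1176 genes higher in both iHep groups and 1177 lower in both, against 389 and 261 for independent lists. In the simulations of unchanged groups limma called 0 genes in both, so they give no reference for these counts. Genes higher in vivo and lower in vitro numbered 94, and 126 went the other way, against 320 and 317 for independent lists. Across genes the log2 differences correlated at r = 0.522, below the 0.601 that shared controls alone gave in the simulations, and their covariance was 2.27 against 0.189, a difference of 2.08. With a separate Pr-mHSC array as the control of each comparison, replicate 2 in vivo and 3 in vitro, 772 genes were higher and 716 lower in both, against 254 and 163 for independent lists, and the covariance was 1.98. With the controls exchanged, 743 were higher and 680 lower, against 190 and 119, and the covariance was 2.10. Each control is then 1 array with a spread taken from the other groups, and with both arrays as controls part of the excess may come from the shared controls. Without Pr-mHSC replicate 2, the genes lower in both numbered 748.

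The distance between hepatocytes and myofibroblasts themselves was given by In-vivo eHep against Pr-mHSC. All 36 plasma proteins rose, with a median of 12.96 (adjusted p = 3.69e-22, and adjusted p = 0.141 with an estimated correlation). Alb rose by 15.26 (SE 0.65, adjusted p = 9.43e-08), from -7.36 ± 0.70 (n = 2) to 7.89 ± 0.31 (n = 3), and Ttr at least 23436-fold. All 24 cytochrome P450 genes rose, with a median of 12.22 (adjusted p = 6.43e-15, and adjusted p = 0.14 with an estimated correlation), as did all 28 genes of the urea cycle and amino acids, with a median of 11.78 (adjusted p = 1.58e-19, and adjusted p = 0.14 with an estimated correlation). Cyp2f2 was at least 20207-fold higher, Cyp3a11 at least 23671-fold and Arg1 at least 15553-fold. The other largest rises were Mup5 (at least 26309-fold), Fabp1 (at least 23918-fold), Serpina3k (at least 27856-fold) and the carboxylesterase gene Ces3a (at least 19675-fold). Of 23 hepatocyte transcription factors, 20 rose and Gata4 fell by 2.30, with a median of 8.25 (adjusted p = 6.32e-10, and adjusted p = 0.14 with an estimated correlation). Hnf4a was at least 7549-fold higher, and Foxa3 rose by 9.43 and Afp by 3.57. Krt19 rose by 2.25 (adjusted p = 0.0217), a call lost with median centring (0.0674), with the other scalings (0.0802 to 0.0914), with slide as a block (0.102), with the replicate block (0.15), with only the groups compared (0.0506), without Pr-mHSC replicate 2 (0.156) and without In-vivo eHep replicate 1 (0.0614) or 2 (0.0576). All 22 genes of fatty acid oxidation rose, with a median of 4.13 (adjusted p = 4.38e-10, and adjusted p = 0.157 with an estimated correlation), of which 20 or 21 were called under the other scalings. All 29 genes of oxidative phosphorylation rose, with a median of 1.61 (adjusted p = 4.15e-08, and adjusted p = 0.278 with an estimated correlation), against 11 called under quantile normalization, 23 under median centring, 8 under normexp and 11 in the authors' matrix.

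Matrix and contractile genes were lower in In-vivo eHep than in Pr-mHSC. Of 32 matrix genes, 30 fell, 1 rose and 1 did not pass, with a median of -6.52 (adjusted p = 6.43e-15, and adjusted p = 0.14 with an estimated correlation). Col1a1 fell by 9.41 and Col5a1 by 9.12. Of 27 genes of activated stellate cells and myofibroblasts, 24 fell, 25 when adjusted over the list alone, with a median of -5.92 (adjusted p = 1.01e-12, and adjusted p = 0.157 with an estimated correlation). Cnn1 fell by 9.81, the collagen cross-linker Lox by 9.35, Acta2 by 7.35 and Vim by 5.92. The neural adhesion gene Ncam1 fell by 9.41, P2ry14 by 9.37 and Robo2 at least 342-fold. Of 21 mesenchymal transcription factors, 13 fell, 14 when adjusted over the list alone, and 2 rose, with a median of -3.04 (adjusted p = 8.46e-06, and adjusted p = 0.14 with an estimated correlation), and Foxf1 and Tcf21 fell by 7.33 and 8.01. In the cell cycle list, 12 of 23 genes fell, with a median of -2.87 (adjusted p = 8.46e-06, and adjusted p = 0.431 with an estimated correlation). Mki67 fell by 3.66 (adjusted p = 0.0245), a call lost without Pr-mHSC replicate 2 (0.0639) or 3 (0.121) and without In-vivo eHep replicate 2 (0.064) or 3 (0.077). The macrophage list was higher in In-vivo eHep, with 16 of 22 genes up, 18 when adjusted over the list alone, and a median of 4.15 (adjusted p = 4.62e-05, and adjusted p = 0.431 with an estimated correlation). Altogether, 7886 genes were higher and 4171 lower in In-vivo eHep. Some of these genes were above background in neither group. Their levels depend on the upper quartile set to 0, which was a signal of 7411 and 6481 in Pr-mHSC. It was 3057, 2298 and 2053 in In-vivo eHep. Cdx2 was such a gene, at -9.58 and -9.39 in Pr-mHSC and -7.94, -7.71 and -8.28 in In-vivo eHep. How many such genes were called was not counted. The higher share of 65.4% became 49.4% with quantile normalization (5466 and 5609) and 47.4% with normexp (4163 and 4619). With slide as a block, 7042 were higher and 3465 lower. Within slides 2 and 3 the plasma protein list had medians of 13.09 and 12.87, the macrophage list 2.09 and 4.36 and the matrix list -8.12 and -6.42.

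How far the induced cells matched the animal's own hepatocytes was asked by In-vivo iHep against In-vivo eHep. Of the most abundant hepatocyte products, Alb (7.05 ± 0.33 against 7.89 ± 0.31, n = 3 each, a log2 difference of -0.85, SE 0.58, adjusted p = 0.268), Ttr (adjusted p = 0.248) and Cyp3a11 (adjusted p = 0.483) did not pass the test, nor did Hnf4a (-0.93, adjusted p = 0.122), Foxa3 (-0.36, adjusted p = 0.686), Gata4 (adjusted p = 0.947) or Afp (adjusted p = 0.976). Metabolic genes were lower in the In-vivo iHep samples. Markers of other liver cells were higher in these samples, as given below. Whether a lower share of hepatocytes accounts for the metabolic falls stays open and was not tested. In the list of the urea cycle and amino acids, 22 of 28 genes fell, 25 when adjusted over the list alone, with a median of -1.78 (adjusted p = 5.92e-07, and adjusted p = 0.406 with an estimated correlation). Under the other scalings, between 12 and 21 of them were called lower. Agxt, which detoxifies glyoxylate, fell by 2.42 and Kynu, an enzyme of tryptophan breakdown, by 2.79. Of 16 genes of glucose and glycogen metabolism, 13 fell, 14 when adjusted over the list alone, with a median of -2.07 (adjusted p = 0.000106, and adjusted p = 0.406 with an estimated correlation). That count of 13 ran from 9 to 13 under the other scalings. Of 14 bile acid genes, 9 fell, 10 when adjusted over the list alone, with a median of -1.94 (adjusted p = 0.000621, and adjusted p = 0.406 with an estimated correlation), including Cyp8b1, which sets the share of cholic acid, by 3.94. Between 6 and 9 bile acid genes were called lower under the other scalings. Of 23 hepatocyte transcription factors, 13 fell, with a median of -1.82 (adjusted p = 0.000187, and adjusted p = 0.406 with an estimated correlation). Tbx3 fell by 3.53 (adjusted p = 0.00777). Among the 5 largest falls, Cyp4a14 fell by 4.37, Dmrta1 by 4.28 and Sult2a7 by 4.41. Of the plasma proteins, 4 of 36 were called lower, 3 when adjusted over the list alone, with a median of -0.89 (adjusted p = 0.00579, and adjusted p = 0.648 with an estimated correlation) that became -0.15 with quantile normalization.

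Lists of macrophage, endothelial, matrix, mesenchymal, fetal liver and cell cycle genes were higher in In-vivo iHep than in In-vivo eHep. In the macrophage list, 19 of 22 genes rose, with 1 lower when adjusted over the list alone and a median of 2.99 (adjusted p = 1.21e-10, and adjusted p = 0.406 with an estimated correlation), and Cd5l rose by 3.52. The list's mean level was 1.69 ± 0.59 in In-vivo iHep (n = 3) and 0.04, -2.91 and -0.36 on the In-vivo eHep arrays. Of 22 endothelial genes, 10 rose, 15 when adjusted over the list alone, with a median of 2.04 (adjusted p = 2.58e-08, and adjusted p = 0.406 with an estimated correlation), Stab1, a scavenger receptor of sinusoids, by 2.45. Of 32 matrix genes, 14 rose, 21 when adjusted over the list alone, and 1 fell, with a median of 2.54 (adjusted p = 2.42e-09, and adjusted p = 0.406 with an estimated correlation). Fbln2 rose by 5.11 and Col1a1 by 5.70 (adjusted p = 0.0128), the latter lost without In-vivo iHep replicate 3 (0.0551). Vim rose by 4.35 (adjusted p = 0.0161), also lost without that array (0.0615) and with only the groups compared (0.054), and Krt19 by 4.13 (adjusted p = 0.00663). Of 21 mesenchymal transcription factors, 9 rose, 11 when adjusted over the list alone, with a median of 2.69 (adjusted p = 6.1e-06, and adjusted p = 0.406 with an estimated correlation), among them Twist1 (at least 8.60-fold) and Twist2 (at least 38.4-fold). In the fetal liver list, 7 of 15 genes rose, with a median of 2.06 (adjusted p = 0.000747, and adjusted p = 0.406 with an estimated correlation), led by Dlk1, a marker of fetal liver progenitors, by 8.24. On the In-vivo iHep arrays the list's mean level was -1.26, -1.94 and -0.72, and Dlk1 was at 3.42, 0.60 and 4.34. Both were lowest on replicate 2, as were the mesothelial markers Upk3b, Msln and Gpm6a, described below with others that were not. Cell cycle genes rose in 13 of 23 cases, 19 when adjusted over the list alone, with a median of 2.95 (adjusted p = 2.42e-09, and adjusted p = 0.406 with an estimated correlation), Bub1, a spindle checkpoint kinase, by 4.99. The list's mean level was 1.32, -1.45 and 1.94 on the In-vivo iHep arrays and -1.21, -2.74 and -2.90 on the In-vivo eHep arrays, so replicate 2 of the former lay below replicate 1 of the latter. Mki67 did not pass (3.03, adjusted p = 0.0501), nor did Acta2 (3.17, adjusted p = 0.0732). Other large rises were the growth factor Ptn (at least 105-fold), the urothelial gene Upk3b (at least 92.2-fold) and Gask1b (at least 48.9-fold).

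The contrast of In-vivo iHep with In-vivo eHep gave 2476 genes higher and 4465 lower, and it was the comparison most open to the treatment of arrays. For 608 of the latter, In-vivo iHep was not above background on any array. The upper quartile set to 0 was a signal of 4754, 3504 and 5803 in In-vivo iHep and 3057, 2298 and 2053 in In-vivo eHep. Genes above background in neither group can therefore read lower in In-vivo iHep. The higher share of 35.7% became 43.7% with quantile normalization (2910 and 3756) and 45.2% with normexp (2242 and 2717). Without In-vivo iHep replicate 3 there were 810 and 1226, without In-vivo eHep replicate 2 there were 1110 and 1628, and without In-vivo eHep replicate 3 there were 1396 and 2017. With slide as a block in limma, the 8 arrays of the 3 slides left 3 residual degrees of freedom and 0 genes were called, with a smallest adjusted p of 0.0505 and 9734 genes at an unadjusted p under 0.05. With the replicate number as a block, limma called 0 genes as well. The same arrays without the slide block gave 5072 calls and 10806 genes at an unadjusted p under 0.05. Every slide holds both groups, so the block leaves the differences as they are and changes only their spread and degrees of freedom. List medians varied between slides 1, 2 and 3: the macrophage list gave 1.27, 5.27 and 2.45, the matrix list 0.29, 4.11 and 2.09, and the cell cycle list 2.40, 1.16 and 5.10.

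**Figure D2:**
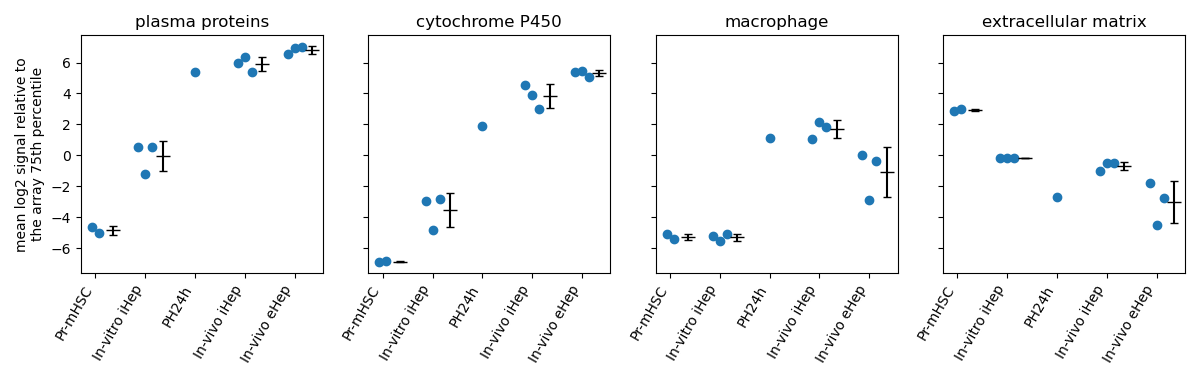
Mean log2 signal of 4 gene lists relative to the 75th percentile of each array; dots are arrays and bars the group mean and SD, with PH24h a single array. Plasma proteins average 5.90 in In-vivo iHep and -0.04 in In-vitro iHep, cytochrome P450 genes 3.83 and -3.53, macrophage genes 1.69 and -5.28, and extracellular matrix genes -0.67 and -0.17.

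In-vitro iHep were set against PH24h to compare induced and primary hepatocytes in culture. Hepatocyte products were mostly lower in the induced cells. Of 36 plasma proteins, 29 fell, 32 when adjusted over the list alone, with a median of -5.80 (adjusted p = 4.6e-14, and adjusted p = 0.43 with an estimated correlation). Serpina3k fell at least 14520-fold and Serpinc1, antithrombin, fell by 11.17, while Ttr did not pass (-1.77, adjusted p = 0.141). Alb fell by 3.13 (SE 0.83, adjusted p = 0.0152) and Hnf4a by 2.16 (adjusted p = 0.0224), and both calls ended with quantile normalization (0.241 and 0.115), with normexp (0.222 and 0.0908), in the authors' matrix (0.246 and 0.104) and with only the groups compared (0.0602 and 0.0578). Of 24 cytochrome P450 genes, 15 fell, 18 when adjusted over the list alone, with a median of -4.87 (adjusted p = 4.77e-09, and adjusted p = 0.43 with an estimated correlation), Cyp1a2 at least 438-fold. Of 28 genes of the urea cycle and amino acids, 20 fell, with a median of -4.28 (adjusted p = 5.92e-09, and adjusted p = 0.43 with an estimated correlation), Agxt at least 1055-fold and Dmgdh at least 1001-fold. Of 19 acute phase genes, 11 fell and 1 rose, with a median of -6.27 (adjusted p = 8.58e-05, and adjusted p = 0.43 with an estimated correlation), Orm1 at least 4384-fold and Crp at least 966-fold. Foxa3 fell by 4.56 and Cyp3a11 by 6.15. The other largest falls were Igfbp1, a hepatic binding protein of growth factors (at least 6188-fold), Fhad1 (at least 4823-fold) and Cyp3a44 (at least 3545-fold).

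Macrophage genes were higher on the PH24h array than in In-vitro iHep, and mesenchymal genes were lower. In the macrophage list, 18 of 22 genes fell in In-vitro iHep, 19 when adjusted over the list alone, with a median of -5.98 (adjusted p = 1.49e-09, and adjusted p = 0.43 with an estimated correlation), Clec4f at least 1591-fold and Cd5l at least 2120-fold. Of 32 matrix genes, 13 rose, 15 when adjusted over the list alone, with a median of 2.53 (adjusted p = 0.000778, and adjusted p = 0.528 with an estimated correlation), Fbln1 at least 205-fold and Thbs2 at least 131-fold. Of 21 mesenchymal transcription factors, 11 rose, 12 when adjusted over the list alone, and 3 fell, with a median of 3.36 (adjusted p = 0.000778, and adjusted p = 0.43 with an estimated correlation), Foxf2 at least 156-fold and Foxf1 at least 44.2-fold. Krt19 rose by 3.33 (adjusted p = 0.0157), and Col1a1 by 5.15 (adjusted p = 0.0464), the latter a call lost with quantile normalization (0.0858), in the authors' matrix (0.0645), with slide as a random block (0.0518) and without In-vitro iHep replicate 1 (0.0796), 2 (0.0799) or 3 (0.0838). The largest rises were Penk, which encodes opioid peptides (at least 2314-fold), Psca (at least 1219-fold), Spink1, a trypsin inhibitor (at least 2480-fold), Clic6 (at least 663-fold) and the imprinted gene Peg3 (at least 712-fold). Afp (0.20, adjusted p = 0.873), Gata4 (adjusted p = 0.0932), Acta2 (adjusted p = 0.198), Vim (adjusted p = 0.482) and Mki67 (4.03, adjusted p = 0.0574) did not pass. There were 4217 genes higher and 4586 lower, a higher share of 47.9% that became 37.0% with median centring (3282 and 5600), 54.9% with quantile normalization (4703 and 3869) and 54.4% in the authors' matrix (4684 and 3926). PH24h is 1 array with no replicate check, so these values compare In-vitro iHep with that array. The Y-linked genes Ddx3y and Eif2s3y were not above background on it while Xist was, so sex may differ from In-vitro iHep too.

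Conversion in the animal and in culture was compared directly in In-vivo iHep against In-vitro iHep. Mature hepatocyte genes were higher in vivo. All 24 cytochrome P450 genes rose, with a median of 7.18 (adjusted p = 1.73e-17, and adjusted p = 0.174 with an estimated correlation), Cyp1a2 at least 4028-fold, Cyp3a25 by 12.92 and Cyp3a11 by 8.37 (SE 0.82, 6.56 ± 0.44 against -1.81 ± 2.10, n = 3 each). Of 28 genes of the urea cycle and amino acids, 27 rose and Glyat did not pass, with a median of 7.94 (adjusted p = 3.62e-24, and adjusted p = 0.174 with an estimated correlation). Mat1a, which makes the methyl donor of the liver, was at least 4874-fold higher and Dmgdh at least 2893-fold. Of 36 plasma proteins, 33 rose, with a median of 6.14 (adjusted p = 4.62e-21, and adjusted p = 0.174 with an estimated correlation), among them Serpina3k (at least 15226-fold), the complement gene C8a (at least 1546-fold) and Ttr (2.39, adjusted p = 0.0138), the last lost with the replicate block (0.0664). Alb (1.93, adjusted p = 0.0287) and Hnf4a (1.34, adjusted p = 0.0398) passed, yet both calls ended with quantile normalization (0.133 and 0.104), with normexp (0.0978 and 0.0771), in the authors' matrix (0.135 and 0.104), with only the groups compared (0.0579 and 0.0824), with the replicate block (0.0876 and 0.151) and without In-vivo iHep replicate 1 (0.067 and 0.107) or 2 (0.0795 and 0.114). The Hnf4a call also ended with median centring (0.0584), with array weights (0.0668) and without In-vitro iHep replicate 1 (0.0572) or 2 (0.117). Foxa3 rose by 7.01. Of 19 acute phase genes, 13 rose, 14 when adjusted over the list alone, with a median of 5.39 (adjusted p = 1.06e-08, and adjusted p = 0.174 with an estimated correlation), Crp at least 3012-fold and Orm1 at least 11628-fold. Igfbp1, Mug2 and the urate oxidase gene Uox were the other largest rises, at least 13450-fold, 6033-fold and 8106-fold.

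Markers of macrophages and endothelium were also higher in In-vivo iHep than in In-vitro iHep. Of 22 macrophage genes, 20 rose, with a median of 7.06 (adjusted p = 1.55e-13, and adjusted p = 0.196 with an estimated correlation), Clec4f at least 2256-fold. Of 22 endothelial genes, 18 rose, 19 when adjusted over the list alone, with a median of 5.86 (adjusted p = 3.94e-12, and adjusted p = 0.174 with an estimated correlation), Fcgr2b at least 1170-fold and Cdh5, the cadherin of endothelium, at least 361-fold. Matrix genes went both ways, 7 up, 8 when adjusted over the list alone, and 11 down, with a median of -0.33 (adjusted p = 0.195). Lum rose by 7.70 and Dcn by 5.11, and Thbs2 fell by 6.50. Among the largest falls, Cubn, an endocytic receptor of absorptive cells, fell by 11.17, Vil1 by 10.73, Psca at least 1720-fold, Clic6 at least 1180-fold and Penk by 10.50. Afp fell by 4.64 (adjusted p = 0.000233). Krt19 (-1.66, adjusted p = 0.0663), Col1a1 (adjusted p = 0.532), Acta2 (adjusted p = 0.664), Vim (adjusted p = 0.306), Gata4 (adjusted p = 0.892) and Mki67 (adjusted p = 0.87) did not pass. In total 3879 genes were higher and 3780 lower, and the higher share of 50.6% became 40.6% with median centring (3342 and 4888).

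The gaps to hepatocytes in the animal and in culture were set side by side in the contrast of In-vivo iHep minus In-vivo eHep with In-vitro iHep minus PH24h. The contrast passed the threshold for 4055 genes on the higher and 5216 on the lower side, with a median of -0.35 over all genes, and the higher share of 43.7% became 55.3% with median centring (4831 and 3904). For plasma proteins the median contrast was 4.88 (adjusted p = 6.79e-11, and adjusted p = 0.794 with an estimated correlation), and 22 of 36 genes passed on the higher side, 23 when adjusted over the list alone. PH24h is a single array whose spread is borrowed from the other groups, so no difference between the settings is called.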

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

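The tests of the macrophage pattern in the second paragraph were chosen only after the result was seen. The contrast of In-vivo iHep minus In-vivo eHep with In-vitro iHep minus PH24h passed the threshold for 4055 genes on the higher and 5216 on the lower side. Among hepatocyte lists, the median of this contrast was 4.88 for plasma proteins, 5.37 for acute phase genes, 3.51 for cytochrome P450, 2.48 for the urea cycle and amino acids, 2.31 for pericentral genes, 1.95 for periportal genes and 1.63 for epithelial junctions. Among lists of other cells, it was 9.29 for macrophages, 6.34 for endothelium, 3.51 for neutrophils, 2.58 for quiescent stellate cells and 1.20 for lymphocytes. It was 1.85 for antigen presentation, 2.07 for the interferon response and -5.98 for Y-linked genes. The ribosomal proteins had a median of 1.17, which became 0.26 with quantile normalization, 0.22 with normexp and 0.25 in the authors' matrix. With an estimated correlation, the adjusted p of these lists was 0.794 or more, and the contrast rests on the single PH24h array, whose spread is borrowed from the other groups and whose scan day and scanner go with its group, so no difference between the settings is called.

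Macrophage and endothelial markers were higher in In-vivo iHep than in In-vivo eHep. A lower share of hepatocytes in the In-vivo iHep samples would raise the markers of every other cell type alike, and the medians over markers above background in both groups were 2.99 for macrophages, 2.04 for endothelium, 1.66 for neutrophils, 1.10 for lymphocytes and 0.203 for erythroid cells, so that macrophages stood 2.79 above erythroid cells (95% interval 0.979 to 4.35 over resampled genes). That interval reaches below 1, the limit set for the test, so a lower hepatocyte share may account for part of the difference and stays open. Macrophages recovered with the In-vivo iHep stay open as well, since the count of 19 of 22 markers called higher restates the pattern and cannot test its source. Cd5l was at 4.03 ± 0.38 and Clec4f at 3.85 ± 0.56 in In-vivo iHep (n = 3), and the labels name no sort or gate. All 22 markers were above background on an In-vivo eHep array as well, 15 were so on a Pr-mHSC array, and 0 belong to another list. A biological difference in the liver's macrophages between the groups stays open and was not tested.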

How the results depend on the processing

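Of 370 recomputed counts, positions and overlaps, 319 stayed within the spread between replicates or within 1.5 times the reported count; the causes of the others were not tested. With median centring, 4876 genes were lower in In-vivo iHep than in Pr-mHSC. With normexp, 2534 were higher in that comparison, 4163 higher in In-vivo eHep than in Pr-mHSC, 2717 lower in In-vivo iHep than in In-vivo eHep and 754 higher in both iHep groups. With slide as a fixed block, 1867 were lower in In-vivo iHep than in Pr-mHSC, and 0 were higher and 0 lower in In-vivo iHep than in In-vivo eHep. At a log2 difference of at least 2, a stricter threshold by construction, the counts were 1783 lower for In-vivo iHep versus Pr-mHSC, 4634 higher and 2663 lower for In-vivo eHep versus Pr-mHSC, 1415 and 1043 for In-vivo iHep versus In-vivo eHep, 2689 lower for In-vitro iHep versus PH24h, and 2549 and 1733 for In-vivo iHep versus In-vitro iHep. Without the filter on dim probes, 12988 genes were higher in In-vivo eHep than in Pr-mHSC and 8205 lower in In-vitro iHep than in PH24h. For In-vivo iHep versus In-vivo eHep, 1544 were higher and 2811 lower with only the groups compared, and 6807 were lower with array weights. The least-squares slope put In-vivo iHep at 0.737 and In-vitro iHep at 0.352 on the axis.

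Leaving out each array in turn gave 2626 to 3889 higher and 1902 to 3162 lower genes for In-vivo iHep versus Pr-mHSC, 1815 to 2507 and 1417 to 1745 for In-vitro iHep versus Pr-mHSC, 5920 to 8237 and 3521 to 4123 for In-vivo eHep versus Pr-mHSC, 810 to 3033 and 1226 to 5540 for In-vivo iHep versus In-vivo eHep, 3339 to 4099 and 3805 to 4240 for In-vitro iHep versus PH24h, 3086 to 3777 and 2933 to 3781 for In-vivo iHep versus In-vitro iHep, and 3211 to 4117 and 3979 to 5944 for the contrast of gaps. Genes higher in both iHep groups numbered 795 to 1234 and genes lower in both 748 to 1244, and the axis positions ran from 0.495 to 0.632 in vivo and 0.207 to 0.298 in vitro. The lowest counts came without Pr-mHSC replicate 2 in the comparison of In-vivo iHep with Pr-mHSC, and without In-vivo iHep replicate 3 in that with In-vivo eHep. Where a group kept 1 array, that array was assumed to vary like the others. PH24h, a single array, could not be left out.

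Replicate numbers are shared by the groups, but over all genes same-numbered arrays did not deviate together: In-vivo iHep and In-vivo eHep correlated at -0.0598, -0.159 and 0.154, and In-vivo iHep and In-vitro iHep at -0.175, -0.167 and -0.136, so arrays did not correlate best with their own number throughout. Single lists differed from this. On replicate 1, which shares slide 1, female-biased liver genes had a mean level of 1.69 in In-vivo iHep and 2.64 in In-vivo eHep, against -3.70, -4.76, -2.38 and -3.99 on the other arrays of these groups, and Xist was above background on replicate 1 alone in both groups. On replicate 3, which shares slide 3, Reg1 read 4.45 in In-vivo iHep and 0.73 in In-vivo eHep, and Zg16 4.77 and 1.32. On the other arrays of these groups Reg1 lay between -6.57 and -5.59 and Zg16 between -7.39 and -5.73. Both genes were picked after their values were seen. Such values leave open that In-vivo iHep and In-vivo eHep of the same number are matched, and the correlations over all genes cannot exclude it. The 2476 higher and 4465 lower calls between these groups come from a fit that does not pair the arrays. With the replicate block, calls numbered 3447 higher and 2284 lower for In-vivo iHep versus Pr-mHSC, 967 and 781 for In-vitro iHep versus Pr-mHSC, 6916 and 3318 for In-vivo eHep versus Pr-mHSC, 0 and 0 for In-vivo iHep versus In-vivo eHep, and 3166 and 2853 for In-vivo iHep versus In-vitro iHep. No paired analysis was possible for the comparison with PH24h and the contrast of gaps because PH24h is a single array.

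With a correlation estimated from the data, camera called 0 of the lists fixed before the data were examined higher and 0 lower in every comparison, where the preset correlation gave 28 and 5 for In-vivo iHep versus Pr-mHSC, 14 and 5 for In-vitro iHep versus Pr-mHSC, 23 and 6 for In-vivo eHep versus Pr-mHSC, 14 and 13 for In-vivo iHep versus In-vivo eHep, 5 and 18 for In-vitro iHep versus PH24h, 27 and 3 for In-vivo iHep versus In-vitro iHep, and 15 and 1 for the contrast of gaps. With fry the counts were, in the same order, 26 and 5, 16 and 4, 26 and 5, 7 and 10, 5 and 17, 27 and 2, and 11 and 1. There were 12 reversals among named genes. With the mean of a gene's probes, Itgam gave 1.73 against Pr-mHSC and 1.64 against In-vitro iHep in In-vivo iHep, Xaf1 gave 2.53 in In-vitro iHep against Pr-mHSC, and Gfap gave 0.0553 in In-vivo iHep against In-vitro iHep. In In-vivo eHep versus Pr-mHSC, Cdx2 gave -0.0113 with quantile normalization and -0.013 in the authors' matrix, and was above background in neither group. In the same comparison, Rpl11 gave -0.10, -0.24 and -0.21 and Rps14 gave -0.36, -0.43 and -0.43 with quantile normalization, with normexp and in the authors' matrix. Of the values of named genes without 1 array, 4026 kept their side of the threshold, 387 lost it and 139 gained it. Signal above background limits the rest: where a group is not above background, only a lower bound of the fold is known.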

Other observations

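The mesothelial, brush border, digestive, kidney and intestinal lists, the Y-linked list with Xist, and the tests of the replicate 2 and brush border patterns were chosen only after the result was seen. Genes with a known sex bias in liver also moved. Of 15 genes with male bias, 13 rose in In-vivo iHep against In-vitro iHep, 14 when adjusted over the list alone, with a median of 7.32 (adjusted p = 1.9e-10, and adjusted p = 0.174 with an estimated correlation). Of 15 with female bias, 4 rose, 2 when adjusted over the list alone, with a median of 3.60 (adjusted p = 0.0405, and adjusted p = 0.668 with an estimated correlation), at a mean level of 1.69, -3.70 and -4.76 on the In-vivo iHep arrays and -5.32 ± 0.38 in In-vitro iHep (n = 3), so that replicate 1 stands apart. The cytochrome P450 list had a median of 7.18 there, so these rises are not particular to genes with a sex bias. The Y-linked genes Ddx3y and Eif2s3y were not above background on the PH24h array and rose at least 20.8-fold and 44.3-fold in In-vitro iHep against it. With Xist added to that list, 2 of 4 genes rose (adjusted p = 0.0188, and adjusted p = 0.15 with an estimated correlation), at a mean level of -1.94 ± 0.28 in In-vitro iHep (n = 3) and -6.56 in PH24h. Xist itself was above background on every In-vitro iHep array (-1.18 ± 0.23, n = 3), beside these Y-linked genes, and on the PH24h array (-3.85). On the Pr-mHSC arrays Xist was not above background (-9.28 and -7.21), while these Y-linked genes were. A difference in sex between In-vitro iHep and Pr-mHSC thus stays open and was not tested. The sex of the animals is not in the labels. Uty, also Y-linked, was not above background on PH24h, while Ddx3y and Eif2s3y were above it on every other array. Y-linked signal absent beside Xist is the pattern of female cells, though here it rests on 1 array. In comparisons with PH24h, sex cannot be told apart from group, and how much it adds to the differences was not tested. Genes of the p53 response and senescence had a mean level of 1.54 ± 0.08 in In-vitro iHep (n = 3), 0.46 ± 0.02 in Pr-mHSC (n = 2), 0.57 ± 0.04 in In-vivo iHep (n = 3), -0.21 ± 0.48 in In-vivo eHep (n = 3) and 1.25 in PH24h. The list did not pass in In-vitro iHep against Pr-mHSC (adjusted p = 0.072, and adjusted p = 0.469 with an estimated correlation), and 5 of 18 genes fell in In-vivo iHep against In-vitro iHep, with a median of -0.94 (adjusted p = 0.0318, and adjusted p = 0.242 with an estimated correlation). Ribosomal proteins had a median of -1.23 in In-vitro iHep against PH24h (adjusted p = 1.59e-05, and adjusted p = 0.528 with an estimated correlation), which turned to 0.02 with quantile normalization.

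Genes called higher in In-vivo iHep and not above background in In-vivo eHep, 428 in number, were mostly lower on replicate 2 of In-vivo iHep. Their median there was -1.07 relative to the mean of replicates 1 and 3 (interquartile range 2.90, against 1.04 over all genes), and 67.8% lay below 0. The same median was 0.165 on replicate 1 and 1.05 on replicate 3 (interquartile range 1.64), each relative to the other arrays, so replicate 3 lay as far the other way. Scaling of replicate 2 as the cause is argued against, since plasma proteins read 0.646 and macrophage genes 0.514 higher on that array. Its quality stays open: its array weight of 0.306 was the lowest of the 12, and its median absolute difference from replicates 1 and 3 was 0.605 and 0.634, against 0.356 between those. A second cell population that gives a different share of the RNA on each array may explain the difference, but the spread of the genes keeps it open. Mesothelial cells are a candidate for it, a hypothesis from markers such as Upk3b (1.51, -1.34 and 2.37 on the In-vivo iHep arrays), Msln (0.83, -0.93 and 1.76) and Gpm6a (2.30, -1.06 and 3.09). Msln and Gpm6a were above background on In-vivo eHep arrays, so they are not among the 428 genes. Relative to replicates 1 and 3, 70.8% of the mesothelial list lay below 0 on replicate 2. Members highest on replicate 2 included Krt7 (-2.95, -1.77 and -2.35), Slpi (2.82, 5.56 and 3.82), Muc16 and Aldh1a2. Of 24 mesothelial genes, 12 had been seen when the list was written, and of the other 12, 7 rose against In-vivo eHep, with a median of 2.72 (adjusted p = 0.00123, and adjusted p = 0.0407 with an estimated correlation). Their median for replicate 2 was -0.88 (95% interval -2.74 to 0.87 over resampled genes), so this stays open. Of the 24, 19 were above background on an In-vivo eHep array, 17 on a Pr-mHSC array and 3 belong to another list, the labels name no sort or gate, and no biological explanation was tested.

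Brush border genes were higher in In-vitro iHep than in Pr-mHSC: 19 of 27 rose, 20 when adjusted over the list alone, with a median of 4.09, Vil1 at least 2508-fold and Slc7a9, an amino acid transporter subunit, at least 849-fold. Of the 20 not seen when the list was written, 12 rose, 13 when adjusted over the list alone (adjusted p = 1.48e-07, and adjusted p = 0.0701 with an estimated correlation). The list was higher against Pr-mHSC in the in-vivo groups too, with 17 of 27 up and 2 down in In-vivo eHep, 18 up when adjusted over the list alone (median 2.21, adjusted p = 0.00251, and adjusted p = 0.629 with an estimated correlation), and 13 up and 1 down in In-vivo iHep, 15 up when adjusted over the list alone (median 1.98, adjusted p = 5.21e-05, and adjusted p = 0.273 with an estimated correlation). With normexp these medians became 0.55 in In-vivo eHep, with 10 up, and 0.42 in In-vivo iHep, with 8 up. Scaling of the arrays as the whole cause is argued against, since the lowest median over the scalings was 1.74, with normexp. That median is over all 27 genes, the 7 seen when the list was written included. It lies well under 4.09, so the size of the rise depends on the correction. Kidney cells in the cultures are argued against, since 2 of 15 abundant kidney transcripts rose (adjusted p = 0.143) and their mean level was -5.38 ± 0.48 (n = 3). Intestinal epithelial cells may be a source, with 11 of 23 abundant intestinal transcripts called higher, 12 when adjusted over the list alone, and 7 of the 17 not seen before (adjusted p = 0.00189, and adjusted p = 0.178 with an estimated correlation), at a mean level of -4.30 ± 0.80, and this stays open, as the share met neither limit set for the test. In In-vivo eHep against Pr-mHSC, 11 of 23 rose too (median 2.08). Mean levels were -4.28 ± 0.35 in In-vivo eHep and -4.54 ± 0.79 in In-vivo iHep (n = 3 each). That count became 7 with quantile normalization, 9 with median centring, 5 with normexp and 7 in the authors' matrix. For In-vitro iHep it was 11, 11, 9 and 11 in the same order. With normexp the medians were 0.48 in In-vivo eHep and 0.67 in In-vitro iHep. Members differed between the groups. Fabp2 read 5.05, 5.68 and 5.84 in In-vivo eHep and -3.39, -2.71 and -3.81 in In-vitro iHep. Lct was above background in In-vitro iHep alone, at -0.39, -5.57 and -0.25. Reg1 and Zg16 read 4.45 and 4.77 on In-vivo iHep replicate 3, against -5.59 or lower on replicates 1 and 2, which raises that group's mean. Counts and means over the list thus cannot tell whether the rise is particular to the cultures, which stays open. Of 13 digestive transcription factors, 8 rose, 9 when adjusted over the list alone, and of the 11 not seen before 6 rose, 7 when adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.0782 with an estimated correlation). The median of all 13 went from 2.22 to 0.88 with normexp, with 5 called, and Cdx2, an intestinal regulator, was at least 38.3-fold higher. Of the 27 brush border genes, 20 were above background on an In-vivo eHep array and 13 on a Pr-mHSC array, 11 of the intestinal and 11 of the kidney genes were so on a Pr-mHSC array, and a change in the cells brought about by conversion in culture stays open and untested.

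For comparisons of 3 arrays with 3, genes were counted in all 10 splits of the 6 arrays. The real split of In-vivo iHep and In-vivo eHep called 4355 genes and that of In-vivo iHep and In-vitro iHep 7686, and the highest other split called 0 in each case, so 1 of 10 splits gave as many genes each time. With 10 splits the share is never under 0.1.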
